A study of Mus musculus with 23 samples.

How the data were processed

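Total RNA from mouse brain tissue was measured on Illumina expression arrays of 25697 probes, 1 array per mouse and 23 arrays in all. Per the labels, RNA was taken up in Trizol, cleaned on RNeasy columns and turned into biotin-tagged cRNA with an Ambion MessageAmp kit. Per the submitters' processing notes, the arrays were read with GenomeStudio 2011.1. For each probe and array, the deposited table that was not normalized holds an intensity, the mean probe signal on a linear scale with no background removed. Beside it, per the file headers, stands a detection p-value that sets the probe against the negative control probes of its array. A second deposited table holds the intensity after processing by the authors. Its quartiles are nearly equal within the 16 embryonic and within the 7 adult arrays but not between these sets, and it contains values below 0, so its background was subtracted and each set was scaled apart. Its column medians lay between 31.1 and 31.3 in the embryonic set and between 16.2 and 16.3 in the adult set, and 27.0% and 23.0% of its values were below 0. The method of scaling is not given in the sources used here, and the table's zero and scale stay unknown beyond these checks. Each of its columns matched the array of its own name best, in 16 of 16 and 7 of 7 cases.

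The analysis started from the signals that were not normalized. They were background-corrected with the normal-exponential model of neqc in limma 3.58.1 (R 4.3.3), with the noise estimated from the detection p-values and an offset of 16, then quantile normalized and put on the log2 scale. The embryonic and the adult arrays were normalized apart, and together for the comparison of the stages. Probes with a detection p under 0.05 on at least 5 embryonic arrays, or at least 3 adult arrays or arrays of the joint set, were kept, which left 14340, 14266 and 16352 probes. Of all probes, 23978 carried 1 gene symbol, 0 several and 1719 none. Entrez numbers matched 23962 probes to the reference gene table (assembly GRCm38.p6, used only for names and for which genes neighbour each other), and 0 symbols changed. The probes covered 16593 genes, 4777 of them with several probes. The files name no genome build, so no coordinates are given.

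Median signal per array lay between 164 and 210 in the embryonic set and between 119 and 143 in the adult set. Detected probes made up 52.3% to 54.8% and 53.1% to 55.1% of each array. The number of arrays limits the precision. No 2 arrays held identical values. The smallest standard deviation of the log2 difference within a pair was 0.25 in the embryonic set and 0.20 in the adult set.

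Linear models were fitted with limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the probes kept and a threshold of 0.05 without a fold minimum. The 16 embryonic arrays shared 1 fit with genotype, sex and litter as terms. The litter is a reading of the first part of each mouse number, since the labels do not state litters. Contrasts were homozygote against wild type, heterozygote against wild type, homozygote against heterozygote, and heterozygote against the mean of the other two genotypes. A fit of sex-by-genotype groups with litter tested whether a genotype effect differed between the sexes. The adult arrays were fitted with genotype alone, and the joint set with sex and litter tested the heterozygote effect at E12.5 against that in the adult. P-values measure effects against the spread between these samples. Errors beside log2 changes are standard errors of the fit, and errors beside group means are standard deviations.

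There were 31 gene lists, of which 25 were tested in embryos, 27 in adults and 31 between the stages. They cover embryonic brain regions, progenitors and neurons, blood, vessel and connective tissue cells, signalling, iron, dopamine, genes associated with restless legs syndrome, neighbours of Meis1, adult cell classes and activity-regulated genes. Each gene was represented by the probe of highest mean signal. Lists with at least 3 measured members were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists of the comparison, and again with the correlation estimated from the data. The fry test was run beside it. It asks whether the members of a list move on balance one way, without comparing them with other genes. Single members were also adjusted over their list alone, with no correction across lists. Calls made only in that way are weaker than calls over all probes.

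Lists, models, thresholds, alternatives and the rule for naming genes were set before the data were examined. In the comparisons of homozygotes or heterozygotes with wild types, the 10 largest changes in each direction past the threshold were named with 1 probe per gene, or all where fewer passed. Where under 5 passed, the 5 smallest p-values were named as well. In the remaining comparisons the 3 largest changes each way, or the 3 smallest p-values, were named. Meis1 was named in each comparison, and up to 4 members of each list with the smallest p-values could be named. Genes whose symbols start with LOC, end in Rik, are accessions or consist of Gm, BC or AI with digits were counted and not named.

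The code was tested on simulated arrays with 50 changed probes per fold size among the probes of each fit. With 14340 probes, 1.5-fold changes were recovered in 56% of cases for homozygote against wild type, in 74% for heterozygote against wild type and in 74% for homozygote against heterozygote. At 2-fold these shares were 94%, 100% and 100%, and at 3-fold and 4-fold 100% in each of the 3 comparisons. For the adult comparison with 14266 probes, 84% of 1.5-fold changes and 100% at each of the larger sizes were recovered. Unchanged probes called in these 4 simulations numbered 8, 6, 10 and 16. The simulated noise was independent between probes and held no litter effects, and all fold sizes were changed at once. The shares therefore check the code and do not give the power to detect changes in the real arrays.

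Alternatives covered background correction, normalization, the authors' values, the probe filter, array weights, the litter and sex terms, the replicate number as a block, males alone, fits on the genotypes compared alone, the joint normalization, the probe chosen per gene, the set test, and each array left out in turn. Added after seeing the data were fits without litter 549, without the 2 dimmest adult arrays, with each E12.5 signal raised to the lowest detected one of its array (probe tests alone), and with erythroid level or array brightness as a covariate. No files were left out. A chip could not serve as a block, because the files name none. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.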

Results

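Gene expression was measured in the brains of C57BL/6J mice that carried 0, 1 or 2 copies of an allele of Meis1, a homeobox transcription factor gene associated with restless legs syndrome. At embryonic stage E12.5 there were 5 wild types (3 males, 2 females), 6 heterozygotes (3 males, 3 females) and 5 homozygotes (3 males, 2 females), each from an embryo of its own. In adult males of 23 weeks there were 3 wild types and 4 heterozygotes. The series title speaks of the ganglionic eminences, whereas the labels call the embryonic tissue forebrain and the adult tissue brain. The labels name Meis1 as the allele for the adult mice, and the change made to the gene is not given in the sources used here. Each array held 25697 probes, and mean signal lay between 561 and 906 in embryos and between 270 and 405 in adults. Detected probes numbered 13446 to 14079 per embryonic array and 13645 to 14153 per adult array.

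The sex labels were checked with sex-linked genes. Xist, which silences an X chromosome in females, lay between 10.44 and 11.17 (log2) in the 7 female embryos, between 4.45 and 4.69 in the 9 male embryos and between 4.29 and 4.39 in the 7 adult males. The Y-linked gene Eif2s3y lay between 8.04 and 9.20 in male and between 4.36 and 4.63 in female embryos, and Kdm5d, also on the Y chromosome, between 6.79 and 7.61 in male embryos, above every female. The Y-linked Uty overlapped between the sexes, at 5.52 to 6.56 in males and 4.94 to 5.66 in females. Of the 5 sex-linked genes listed, 4 had a probe. The embryos came from 4 litters, as read from the mouse numbers. The first principal component held 39.6% of the variance, and litter accounted for 91.3% of it. Litter 549 held 2 heterozygotes, 2 homozygotes and 0 wild types, so it gives no comparison with wild types within itself.

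The comparison of homozygous with wild type forebrain asked what 2 copies of the allele change at E12.5. Meis1 itself was the first check of the labels. Its signal fell by 1.22 ± 0.12 (SE, 5 homozygotes and 5 wild types) on the log2 scale, to 0.430 of the wild type level (adjusted p = 0.000285). Mean log2 signal was 9.96 ± 0.17 (SD, n = 5) in wild types and 8.78 ± 0.23 (SD, n = 5) in homozygotes, and each of the 5 homozygotes lay below each wild type. Where the single Meis1 probe lies relative to the altered part of the gene is not known. Within litters, the change was -1.19 (litter 509), -1.10 (542) and -1.41 (551). With males alone (3 against 3) it was -1.24, with adjusted p = 0.109.

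**Figure D1:**
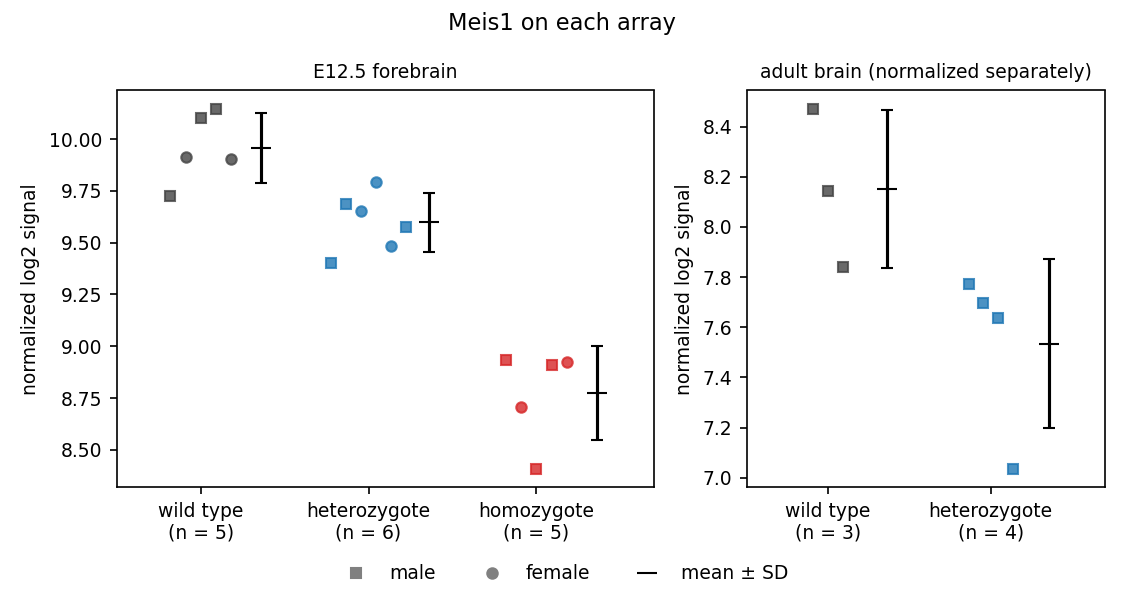
Meis1 log2 signal per array by genotype, in E12.5 forebrain (left, 5 wild types, 6 heterozygotes and 5 homozygotes) and adult brain (right, 3 wild types and 4 heterozygotes), with mean ± SD, squares for males and circles for females. The embryonic means are 9.96, 9.60 and 8.78, and the adult means 8.15 and 7.54.

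Genes of platelets and their precursors, the megakaryocytes, made up most of the remaining changes in homozygotes. Ppbp, a chemokine of platelet granules, fell by 2.79 ± 0.23 (SE, 5 against 5) on the log2 scale (adjusted p = 8.74e-05), and by its second probe, not above background on any of the 5 homozygote arrays, it was at least 3.65-fold higher in wild types (adjusted p = 0.000285). Treml1, a platelet granule receptor, fell by 2.16 ± 0.25 (adjusted p = 0.00164), and Gp9, part of the platelet receptor for von Willebrand factor, fell by 1.36 ± 0.19 (adjusted p = 0.00849). Alox12, the platelet arachidonate 12-lipoxygenase, fell by 1.34 ± 0.19 (adjusted p = 0.00879). Each of the 4 genes was lower in all 5 homozygotes than in any wild type and was detected on all 5 wild type arrays. Among homozygotes, Ppbp, Treml1 and Gp9 were each detected on 1 of 5 arrays and Alox12 on 4 of 5, so the first 3 of these changes are measured against a group near background. The changes had the same sign within each litter that held both genotypes, from -2.01 to -3.18 for Ppbp, from -1.58 to -2.26 for Treml1, from -0.95 to -1.48 for Gp9 and from -0.94 to -1.65 for Alox12. Without homozygote male replicate 2, Gp9 (adjusted p = 0.0716) and Alox12 (adjusted p = 0.0921) missed the threshold, as did Alox12 without wild type female replicate 2 (adjusted p = 0.0501).

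**Figure D2:**
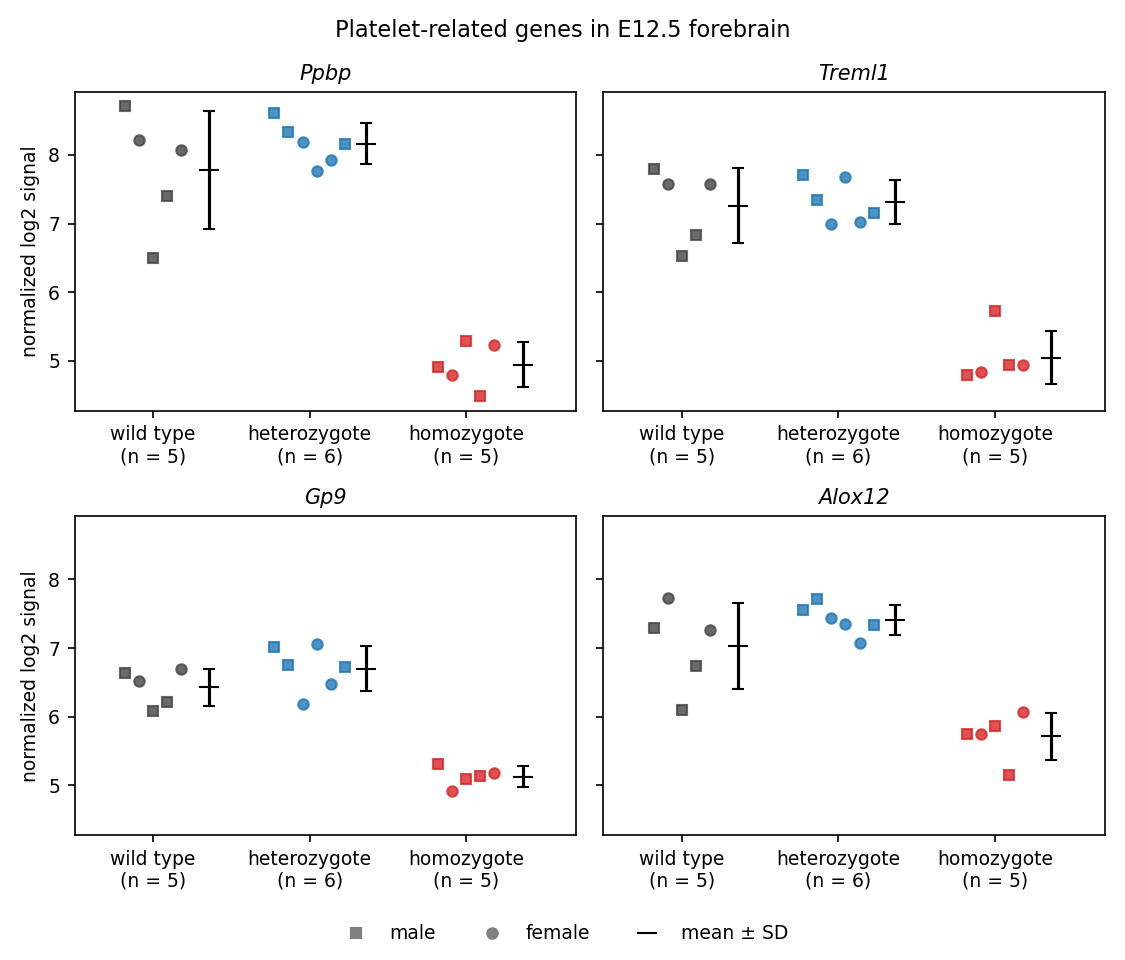
Log2 signal per array of Ppbp, Treml1, Gp9 and Alox12 in E12.5 forebrain by genotype (5 wild types, 6 heterozygotes and 5 homozygotes), with mean ± SD. Ppbp averages 7.78 in wild types, 8.17 in heterozygotes and 4.94 in homozygotes.

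In the list of megakaryocyte and platelet genes, 12 of the 13 measured members were lower in homozygotes, with adjusted p = 7.46e-08 by camera. This became adjusted p = 0.4995 with an estimated correlation, while fry gave adjusted p = 0.0418. With genotypes permuted within litters, 5 of 100 splits gave the list as small a p. Over all probes 3 members fell. By contrast, 7 fell and 1 rose adjusted over the list alone. Pf4, another platelet chemokine, fell by 1.09 ± 0.26, Gp5, a further part of the receptor for von Willebrand factor, fell by 0.77 ± 0.20, and Itga2b, the platelet integrin for fibrinogen, fell by 0.70 ± 0.21. Vwf, which codes for von Willebrand factor itself and is also made by endothelium, rose by 0.39 ± 0.14. Gp5, Itga2b and Vwf lie outside the rule for naming and were chosen after their values were seen. Red cell genes did not pass as a list: 8 of 12 were higher (adjusted p = 0.496).

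**Figure D3:**
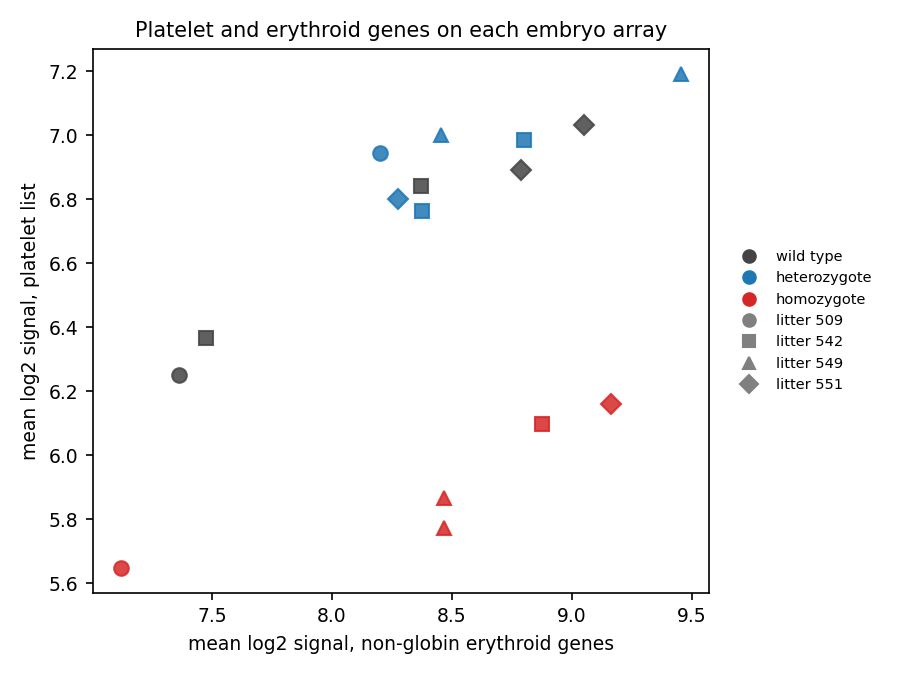
Mean log2 signal of 13 platelet genes against that of 8 red cell genes other than globins, 1 point per E12.5 forebrain array, coloured by genotype with a marker for each litter. Platelet means lie between 5.65 and 6.16 in homozygotes, 6.25 and 7.03 in wild types and 6.76 and 7.19 in heterozygotes, while red cell means overlap.

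The one gene that rose was Lipa, the lysosomal acid lipase, by 0.75 ± 0.12 (SE, 5 against 5), or 1.69-fold, with adjusted p = 0.0355. Each of the 5 homozygotes was above 6.51 (log2) while wild types lay between 5.92 and 6.52 for Lipa, and within litters the change was 0.74 (509), 0.32 (542) and 1.23 (551). The Lipa call held in 3 of 16 fits with 1 array left out, those without wild type male replicate 1, wild type female replicate 2 or homozygote female replicate 2, and adjusted p ranged from 0.0290 to 0.488. It was also lost in 11 of 17 other alternatives, with changes from 0.32 to 0.90 and adjusted p up to 0.843. In all, 1 probe rose and 6 fell among 14340, covering 6 genes. At an unadjusted p under 0.05 there were 1696 probes by limma, where 717 would be the average without any effect. Of 100 random splits of the same arrays, the real one among them, 6 gave as many (highest other 2207). Chance was thus not excluded for this count.

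Connective tissue genes of the meninges and pericytes were higher as a list in homozygotes, with 17 of 21 positive and adjusted p = 0.00786 by camera, but adjusted p = 0.764 with an estimated correlation. None passed singly, that is 0 over all probes and 0 adjusted over the list alone by limma, with the transcription factor genes Foxc1 at 0.57 ± 0.17 and Twist1 at 0.58 ± 0.22, the collagen gene Col1a1 at 0.69 ± 0.22 and the pericyte receptor gene Pdgfrb at 0.33 ± 0.14. The call ended without homozygote female replicate 2 (adjusted p = 0.173), homozygote male replicate 3 (0.0592), wild type female replicate 2 (0.0571) or wild type male replicate 2 (0.244). Macrophage genes were lower in 11 of 13 cases (adjusted p = 0.139). Tyrobp, a signalling adaptor of macrophages, fell by 0.45 ± 0.13, the one member that passed adjusted over the list alone, against 0 over all probes.

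Region genes of the forebrain did not move as lists in homozygotes. In the lateral ganglionic eminence and its striatal descendants 9 of 19 members were positive (adjusted p = 0.872), in the medial ganglionic eminence 7 of 12 (adjusted p = 0.849), in the dorsal pallium 6 of 14 (adjusted p = 0.849), and in the cortical hem and choroid plexus 8 of 17 (adjusted p = 0.872). For diencephalon, midbrain and hypothalamus the figures were 12 of 16 (adjusted p = 0.139), for Hox genes 2 of 3 (0.806) and for eye genes 3 of 7 (0.620). Singly, 3 region genes passed adjusted over the list alone and 0 over all probes. Tac1, the precursor of substance P, fell by 0.52 ± 0.12, Sst, which codes for somatostatin, fell by 0.69 ± 0.20, and Irx5, a homeobox gene of the diencephalon list, rose by 0.50 ± 0.14.

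Radial glia and progenitor genes were positive in 12 of 19 cases (adjusted p = 0.570), young neuron genes in 10 of 19 (0.818), cell cycle genes in 12 of 20 (0.620) and p53 and cell death genes in 9 of 13 (0.750). Endothelial genes stood at 10 of 21 (0.667), hypoxia and glycolysis at 16 of 24 (0.104), retinoic acid signalling at 5 of 8 (0.139) and hedgehog signalling at 4 of 5 (0.337). Epas1, a hypoxia-inducible factor, rose by 0.68 ± 0.16 and Gli3, a transcription factor of the hedgehog pathway, rose by 0.57 ± 0.17, each adjusted over the list alone, against 0 in either list over all probes. Iron handling genes stood at 10 of 14 (0.542), the dopamine system at 4 of 9 (0.950) and the sex-linked genes at 3 of 4 (0.337). Genes associated with restless legs stood at 2 of 5 (0.340) and the TALE homeobox family, to which Meis1 belongs, at 7 of 9 (0.849). In each of these last lists Meis1 was the 1 member that passed, over all probes and adjusted over the list alone. Among neighbours of Meis1 on its chromosome 13 of 20 were positive (0.481), and Etaa1, a replication stress protein gene, rose by 0.44 ± 0.12 adjusted over the list alone, against 0 over all probes. In 8 of the 25 lists median, mean and test differed in sign, none of them called: the TALE family, both ganglionic eminence lists, dorsal pallium, cortical hem, young neurons, endothelium and the dopamine system.

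The comparison of heterozygous with wild type forebrain asked what 1 copy of the allele changes. Meis1 was at -0.40 ± 0.11 (SE, 6 heterozygotes and 5 wild types), with a mean of 9.60 ± 0.14 (SD, n = 6). It missed the threshold over all probes (limma adjusted p = 1.00) and fell adjusted over the list alone (adjusted p = 0.0308 in the TALE family and 0.0171 among genes associated with restless legs). Within litters it was -0.31 (509), -0.50 (542) and -0.16 (551). Over all probes limma called 0, with 474 probes at an unadjusted p under 0.05, where 717 would be the average without any effect. As many or more came from 71 of 100 random splits of the same arrays. Of the 5 genes with the smallest p-values, the 4 that were lower are given here, and the 1 that was higher is not printed, for a reason unrelated to its value. The first was Borcs7, a subunit of a complex that moves lysosomes (-0.64 ± 0.14, detected on 3 of 6 heterozygote arrays). The others were the potassium channel gene Kcna3 (-0.47 ± 0.12, detected on 4 of 6 heterozygote arrays), the GABA receptor subunit gene Gabrb2 (-0.45 ± 0.12, detected on 1 of 6 and 3 of 5) and the lipid transfer protein gene Mttp (-0.46 ± 0.12).

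Platelet and red cell genes were higher as lists in heterozygous than in wild type forebrain by camera. All 13 platelet genes (adjusted p = 1.02e-06) and all 12 red cell genes (adjusted p = 0.00201) were positive, and both calls had adjusted p = 0.517 with an estimated correlation. Positive too were 15 of 21 connective tissue genes (adjusted p = 0.0267) and 16 of 24 hypoxia and glycolysis genes (adjusted p = 0.0479). These became adjusted p = 0.517 with an estimated correlation, as did young neuron genes, which were lower with 5 of 19 positive (adjusted p = 0.0346). Limma passed 0 members of these 5 lists, over all probes or adjusted over the list alone. As many lists or more passed in 25 of 100 random splits of the embryos. The red cell call ended without heterozygote female replicate 2 (adjusted p = 0.0963) or wild type male replicate 3 (0.224), and the platelet call held with any 1 array left out. For connective tissue genes it ended without heterozygote female replicate 1 or 2, heterozygote male replicate 2, homozygote female replicate 1, wild type female replicate 2 or wild type male replicate 2 (adjusted p from 0.0740 to 0.545). Young neuron genes lost theirs without heterozygote female replicate 2, heterozygote male replicate 1 or 3, homozygote female replicate 1, wild type female replicate 2 or wild type male replicate 2 or 3 (0.0963 to 0.261). The hypoxia call held only without homozygote male or female replicate 2, heterozygote male replicate 1, heterozygote female replicate 3 or wild type male replicate 1, and otherwise reached up to 0.206.

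Homozygous was also compared with heterozygous forebrain, which asked what the second copy of the allele adds. Meis1 fell by 0.82 ± 0.11 (SE, 5 against 6; adjusted p = 0.00412), and the change within litters ran from -0.61 (542) to -1.25 (551). Ppbp fell by 3.22 ± 0.21 (adjusted p = 2.31e-06), Treml1 fell by 2.29 ± 0.22 and Alox12 fell by 1.68 ± 0.17 (adjusted p = 0.000186 for both). Heterozygotes detected all 3 on 6 of 6 arrays. Of 14340 probes 10 fell and 0 rose (limma; 1190 at an unadjusted p under 0.05), covering 8 genes and 1 probe without a symbol. Beyond the rule for naming, the remaining 4 genes were chosen after their values were seen: Gp9 (-1.58 ± 0.16), Pf4 (-1.63 ± 0.23), Gp5 (-1.23 ± 0.18) and Mpig6b, an inhibitory receptor of megakaryocytes (-1.02 ± 0.16), all fell. All 13 platelet genes were lower (adjusted p = 2.66e-22, and adjusted p = 0.0250 with an estimated correlation), and 10 fell adjusted over the list alone, against 5 over all probes.

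Macrophage genes were lower in homozygous than in heterozygous forebrain as a list (9 of 13, adjusted p = 0.00382, but adjusted p = 0.627 with an estimated correlation). Of these, 4 fell adjusted over the list alone and 0 over all probes: Tyrobp (-0.54 ± 0.11), the immunoglobulin receptor subunit gene Fcer1g (-0.54 ± 0.13), the lysozyme gene Lyz2 (-0.47 ± 0.12) and the complement gene C1qb (-0.39 ± 0.12). The call ended without homozygote female replicate 1 (adjusted p = 0.0564). Without homozygote male replicate 2, 6 probes passed. Without litter 549, chosen after seeing the data, 2 passed and Meis1 was at -0.84 with adjusted p = 0.163; with males alone it was at -0.64 with adjusted p = 0.569.

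A further contrast asked whether heterozygotes lay midway between wild types and homozygotes on the log2 scale. A gene midway in linear signal would already lie above that midpoint, so part of a departure can come from the scale. Mean log2 signal in heterozygotes was not below that in wild types for Ppbp (8.17 against 7.78), Treml1 (7.32 against 7.26) or Alox12 (7.41 against 7.03). Ppbp read 1.83 ± 0.18 above the midpoint (SE, 6 heterozygotes, 5 wild types and 5 homozygotes; adjusted p = 0.000728), Alox12 1.01 ± 0.14 (adjusted p = 0.0185) and Treml1 1.21 ± 0.20 (adjusted p = 0.0462). Gp9, chosen after its values were seen, read 0.90 ± 0.14 above it (adjusted p = 0.0446). As Ppbp, Treml1 and Gp9 were detected on 1 of 5 homozygote arrays each, their departures are not exact. With every signal raised to the lowest detected one of its array, a fit chosen after the result was seen, Ppbp lay 1.65 ± 0.20 (adjusted p = 0.00885) and Alox12 1.00 ± 0.14 (adjusted p = 0.0197) above the midpoint. Treml1 (adjusted p = 0.128) and Gp9 (adjusted p = 0.0711) then missed the threshold. Meis1 was at 0.21 ± 0.09 (adjusted p = 1.00). Over all probes 6 passed, 6 above and 0 below by limma, with 400 at an unadjusted p under 0.05. All 13 platelet genes were above the midpoint (adjusted p = 2.24e-28, and adjusted p = 0.0108 with an estimated correlation), 10 of them past the threshold adjusted over the list alone and 3 over all probes. Ppbp passed with any 1 array left out. Treml1 did so only without heterozygote female replicate 1, homozygote male replicate 2 or wild type female replicate 2, and otherwise had adjusted p from 0.0514 to 0.310. Alox12 missed the threshold without heterozygote female replicate 2, any 1 heterozygote male, homozygote male or female replicate 1, or wild type male replicate 3 (adjusted p from 0.0532 to 0.168). The count was 2 without any 1 of homozygote male replicate 1, heterozygote male replicates 1, 2 and 3, homozygote female replicate 1 and heterozygote female replicate 2, and 3 without any 1 of wild type female replicate 1 and wild type male replicates 2 and 3. It was 0 by limma without litter 549 (adjusted p of Ppbp 0.257).

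Lists of other cell types also lay off the midpoint in heterozygotes. Red cell genes were above it in 12 of 12 cases (adjusted p = 0.00325) and macrophage genes in 10 of 13 (adjusted p = 0.00210; 3 passed adjusted over the list alone, 0 over all probes), whereas dorsal pallium genes were below it in 14 of 14 cases and young neuron genes in 15 of 19 (adjusted p = 0.0178 for both). With an estimated correlation the adjusted p was 0.737 for red cell, pallium and young neuron genes and 0.536 for macrophage genes. The red cell call ended without heterozygote female replicate 2, heterozygote male replicate 1 or 3, homozygote female replicate 1 or wild type male replicate 3 (adjusted p from 0.06001 to 0.365), and the macrophage call without homozygote female replicate 1 (0.127). The young neuron call ended without any 1 of those 5 arrays or wild type female replicate 2 (0.0776 to 0.375), and the pallium call without heterozygote female replicate 1 or 2, heterozygote male replicate 1 or 3, homozygote female replicate 1, wild type female replicate 2 or wild type male replicate 2 or 3 (0.0509 to 0.207).

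The homozygote and heterozygote changes were set against each other across 14340 probes, which share their wild types and are not independent replicates. Pearson's r was 0.564 and Spearman's coefficient 0.574. In 100 draws the residuals of the fit, that is the signals without the fitted effects, were shuffled over all embryonic arrays and fitted again. The means over these draws were 0.559 and 0.538. In 56 of the 100 draws Pearson's r was as large. Of the 7 probes called in homozygotes, 2 had the same sign in heterozygotes.

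Both sexes were sampled to ask whether the genotype effect differs between them. Limma called 0 probes for the homozygote effect (433 at an unadjusted p under 0.05, smallest adjusted p = 0.999) and 0 for the heterozygote effect (390, smallest adjusted p = 1.00). Meis1 differed by -0.05 ± 0.25 and -0.14 ± 0.26 (males minus females). The smallest p-values for homozygotes (3 and 2 per sex against 3 and 2) belonged to Alkbh5, an RNA demethylase gene (0.99 ± 0.21), Atp6v1b1, a proton pump subunit gene (0.99 ± 0.22), and the ribosomal protein gene Rpl22l1 (1.52 ± 0.35). For heterozygotes (3 and 3 against 3 and 2) they belonged to Nckap1l, a regulator of actin in blood cells (-1.16 ± 0.23), Ociad2 (1.07 ± 0.23) and Pigc, an enzyme gene of membrane anchor synthesis (-0.89 ± 0.20), whose second probe had the opposite sign (0.44 ± 0.37).

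In adult brain the question was whether 1 copy of the allele changes expression in grown males. Meis1 was at -0.62 ± 0.19 (SE, 4 heterozygotes and 3 wild types), with means of 7.54 ± 0.34 (SD, n = 4) and 8.15 ± 0.32 (SD, n = 3), and each of the 4 heterozygotes lay below each wild type. It missed the threshold over all probes (limma adjusted p = 0.386) and fell adjusted over the list alone (adjusted p = 0.0484). Doc2g, a gene of olfactory bulb neurons, was at 1.22 ± 0.18, with its second probe at 0.45 ± 0.13 (limma adjusted p = 0.285 and 0.380). Further small p-values belonged to Tnfrsf25, a death receptor gene (0.63 ± 0.11), Ska2, a gene of chromosome segregation (-0.51 ± 0.09), D3Ertd751e (at least 1.29-fold lower) and Ppbp (at least 1.25-fold lower), both detected on 0 of 4 heterozygote arrays. Limma called 0 probes. At an unadjusted p under 0.05 there were 1524, where 713 would be the average without any effect. Of the 35 ways to split these arrays, 2 gave as many, the real one among them (highest other 2020). Chance was thus not excluded for this count. Without heterozygote replicate 2 limma called 1 probe, Doc2g (1.37, adjusted p = 0.0247), and with median scaling 1 (adjusted p = 0.0168).

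Activity-regulated immediate early genes, which neurons switch on within minutes of firing, were higher in adult heterozygotes. Of 12 measured members 11 were positive, with a median of 0.38 (adjusted p = 1.49e-07 by camera, but adjusted p = 0.341 with an estimated correlation, and fry adjusted p = 0.0735). Adjusted over the list alone 9 rose, against 0 over all probes. Arc, a regulator of synaptic strength, rose by 0.85 ± 0.17 (SE, 4 against 3), the transcription factor gene Junb by 0.76 ± 0.13, the Fos family gene Fosb by 0.42 ± 0.10, and the zinc finger gene Egr2 by 0.53 ± 0.13. The list call held with any 1 array left out. Of the 35 ways to split these arrays, 2 gave the list as small a p.

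**Figure D4:**
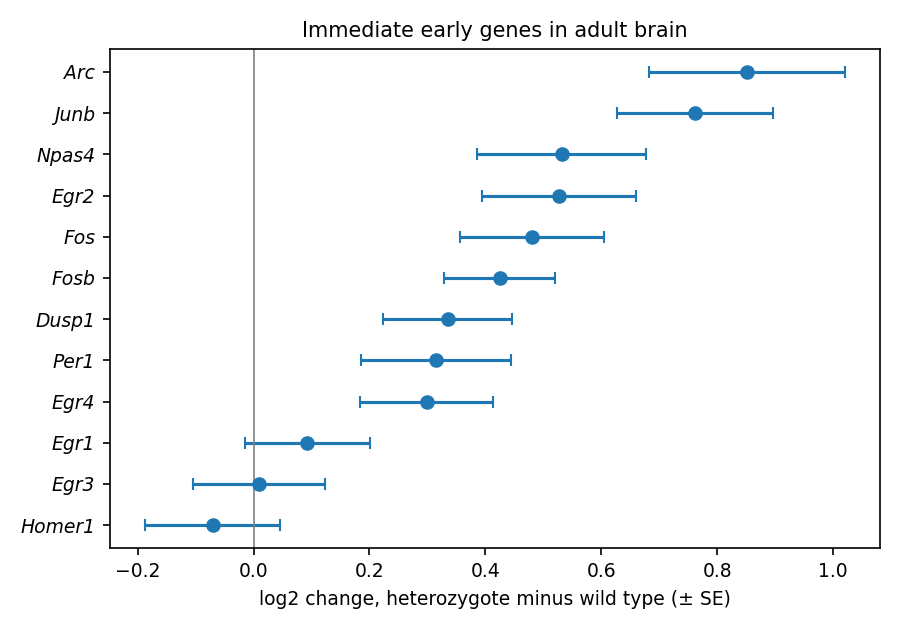
Log2 change (heterozygote minus wild type) of the 12 measured immediate early genes in adult brain, points with ± SE from 4 heterozygotes and 3 wild types. Of these, 11 lie above 0, with Arc at 0.85 and Junb at 0.76.

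Genes that mark the olfactory bulb, thalamus, cerebellum or pituitary did not move as a list in adult heterozygotes, with 16 measured (adjusted p = 0.687). Of these, 3 rose and 3 fell adjusted over the list alone, against 0 over all probes. The list pools several regions and camera tests for a shift in one direction. Opposite changes in different regions could therefore cancel, and the list test cannot exclude them. Doc2g, Th, the rate-limiting enzyme of dopamine synthesis (0.74 ± 0.16), and Cdhr1, a cadherin of the olfactory bulb (1.31 ± 0.32), rose. Gabra6, a GABA receptor subunit of cerebellar granule cells, fell by 0.91 ± 0.22, the neurogenic factor Neurod1 fell by 0.48 ± 0.13, and Zic1, a cerebellar transcription factor chosen after its values were seen, fell by 0.56 ± 0.19. In the dopamine list 6 of 11 were positive (adjusted p = 0.687) and Th was the member that rose adjusted over the list alone.

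No other adult list passed. Oligodendrocyte genes were positive in 7 of 14 cases (adjusted p = 0.643), astrocyte genes in 5 of 12 (0.687), striatal projection neuron genes in 9 of 13 (0.643) and interneuron genes in 6 of 10 (0.333). Htr3a, a serotonin receptor of interneurons, rose by 0.41 ± 0.09 adjusted over the list alone. Iron handling genes were positive in 4 of 13 cases (0.298), and Ireb2, a sensor of cellular iron, fell by 0.44 ± 0.11 adjusted over the list alone. Genes associated with restless legs were positive in 1 of 5 cases (0.333), TALE genes in 5 of 7 (0.946), macrophage genes in 7 of 15 (0.960), platelet genes in 3 of 8 (0.506) and connective tissue genes in 8 of 18 (0.687). In the last 2 lists Ppbp and Lum, the latter at -0.47 ± 0.11, fell adjusted over the list alone. Each of these single calls stands against 0 over all probes. In 7 of the 27 adult lists, all of them without a call, median, mean and test differed in sign: TALE, radial glia, cell cycle, endothelium, macrophage, hypoxia and neighbours of Meis1.

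The heterozygote effect at E12.5 was set against that in the adult, though stage, tissue and array set differ together. Immediate early genes differed as a list, with 3 of 12 positive (embryo minus adult; adjusted p = 8.55e-06, but adjusted p = 0.0830 with an estimated correlation), and 6 of 100 permutation splits gave as small a p. In this contrast 4 were lower adjusted over the list alone, against 0 over all probes: Arc at -0.91, Npas4 at -0.73, Junb at -0.66 and Egr2 at -0.63. Platelet genes were positive in 14 of 14 cases (adjusted p = 0.000138, but adjusted p = 0.357 with an estimated correlation; 7 of 100 permutation splits gave as small a p), and Ppbp, at 1.08 ± 0.28, passed adjusted over the list alone. Ppbp was detected on 0 of 4 adult heterozygote arrays, so its difference is not exact. Meis1 differed by 0.27 ± 0.23 (6 and 5 embryos, 4 and 3 adults; limma adjusted p = 0.842). Limma called 0 of 16352 probes, with 1108 at an unadjusted p under 0.05. The smallest p-values belonged to Dydc2 (0.77 ± 0.13, limma adjusted p = 0.118) and Pramel27 (0.70 ± 0.13), both detected on 0 of the embryonic arrays, and D3Ertd751e (0.72 ± 0.14). As D3Ertd751e was detected on 0 of 4 adult heterozygote arrays, none of these differences is exact. Without adult wild type replicate 1, 4 probes passed, Dydc2 among them (0.90, adjusted p = 0.00322), and without adult heterozygote replicate 2, 1 passed.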

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

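The tests of blood content, litter, array brightness and the neighbours of Meis1 were chosen after the result was seen. So were the splits within litters, and the splits for the heterozygote platelet list and for both lists between the stages. The remaining splits and the tests on regional markers were fixed before they were run. Not all of these were independent of the data, since the regional pattern had already been seen in them. The platelet and immediate early lists, split by themselves, are among the lists called in the main tests.

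Splits of the same arrays into groups of the same sizes, the real one counted among them, asked how often chance gives as many calls. For homozygote against wild type 1 of 100 splits, the real one, reached its 7 probes (highest other 2). For homozygote against heterozygote it was 3 of 100 (10 probes, highest other 12), and for the departure from the midpoint 3 of 100 (6 probes, highest other 112). Why that split gave 112 calls was not tested. These splits ignored the litters, so genotypes were also permuted among the embryos of each litter. Then 2 of 100 splits reached 7 probes (highest other 7), 1 of 100 reached 10 (highest other 7) and 2 of 100 reached 6 (highest other 6). Few splits of either kind thus reached these 3 counts. As 100 splits were drawn and other splits reached some of the counts, chance is made less likely but not excluded. Where limma called 0 probes, any split gives at least as many, so the figures of 100 of 100 for heterozygotes at E12.5 (highest other 2), 35 of 35 in the adult (highest other 4) and 100 of 100 between the stages (highest other 9) decide nothing.

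Chance was not excluded for the numbers of lists called at the preset correlation. As many came from 58 of 100 splits for homozygote against wild type (2 lists, highest other 12), 25 of 100 for heterozygote against wild type (5, highest other 11) and 80 of 100 for homozygote against heterozygote (2, highest other 13). The figures were 23 of 100 for the midpoint (5, highest other 12), 22 of 35 in the adult (1, highest other 2) and 55 of 100 between the stages (2, highest other 11).

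For the platelet list by itself, 1 of 100 permutation splits, the real one, gave as small a p in homozygotes against wild types (camera p = 2.98e-09, smallest other 6.00e-08), against heterozygotes (1.06e-23, smallest other 3.61e-20) and against the midpoint (8.98e-30, smallest other 4.98e-11). Within litters the permutation figures were 5 of 100 (smallest other 1.43e-14), 2 of 100 (smallest other 1.96e-24) and 1 of 100 (smallest other 3.32e-19), so chance was not excluded there for the list in homozygotes against wild types. In heterozygotes against wild types 4 of 100 permutation splits, not restricted to litters, gave the list as small a p (4.09e-08, smallest other 7.03e-13).

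Platelet genes were lower in homozygous forebrain, by 0.75 ± 0.16 on the log2 scale over 13 genes (a change of -0.75, 95% interval -1.12 to -0.38), though the list had adjusted p = 0.4995 with an estimated correlation, 3 of the 13 passed over all probes by limma and Vwf was higher (0.39). Less blood in the tissue would lower red cell genes alike, yet the mean of 8 red cell genes other than globins was 0.210 higher (interval -0.65 to 1.07), and platelet minus red cell genes stood at -0.96 (interval -1.52 to -0.39). Litter as the whole source is argued against by the change within each litter that holds both genotypes, of which the smallest was -0.508. A hypothesis left open is that fewer megakaryocytes or platelets reached the tissue of homozygotes, which may follow from a role of Meis1 in that lineage. It was not tested on blood or liver, and in heterozygotes all 13 platelet genes were positive along with all 12 red cell genes (adjusted p = 0.517 for both with an estimated correlation, 0 members past the threshold by limma, 474 probes at an unadjusted p under 0.05).

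Immediate early genes were higher in adult heterozygotes by 0.38 ± 0.07 on average (camera adjusted p = 0.341 for the list with an estimated correlation). The list of regional genes was not called (camera adjusted p = 0.687) and had 3 members higher and 3 lower adjusted over the list alone. As that list pools regions that could move in opposite directions, its test does not speak against a regional difference. With array brightness in the model the mean change of the immediate early genes was 0.35 ± 0.09, so brightness did not remove it. Camera gave adjusted p = 5.74e-06 at the preset correlation, not repeated with an estimated one. Brightness ran with genotype, though, with mean signal from 270 to 354 in heterozygotes and from 344 to 405 in wild types. With so few arrays the model separates them only in part, so this is weak ground against brightness as the source. For regional makeup, a score of 4 bulb and 10 cerebellar markers, listed without those seen before, was put in the model. The mean change was then 0.297 ± 0.08, so that score did not remove it. The score covers bulb against cerebellum alone and its bulb markers moved both ways, so it cannot decide on regional makeup as the source. Whether the pieces differed in regional makeup could not be decided, as that score was 0.406 higher in heterozygotes (exact permutation p = 0.171, two-sided, 35 splits), and 2 of 4 bulb markers (Kctd12 at -0.39 and Trh at 0.48, chosen after their values were seen) and 2 of 10 cerebellar markers were positive. Chance was not excluded, since 2 of 35 splits gave the list as small a p (5.51e-09, smallest other 2.47e-12), and an effect of genotype or of handling before death stays open.

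The 10 measured genes on each side of Meis1 had a median absolute t of 1.25 in homozygotes, against 0.993 in the median of 9284 windows elsewhere. This lay at percentile 84.9, between the bounds set for and against an effect of the allele or its flanking DNA, so the test decided neither way. Within the window Etaa1 (0.44) and Fignl1 (-0.37) passed at an adjusted p of 0.0321. Flanking DNA from another strain may differ between the genotypes, but no test here separates it from an effect of the allele, and no technical source was tested.

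Some arrays stood apart from their group. Treml1 was at 5.72 (log2) in homozygote male replicate 2, against 4.80 to 4.94 in the other homozygotes. Mttp was at 5.94 in heterozygote male replicate 2, against 5.37 to 5.58. Ska2 was at 5.54 in adult heterozygote replicate 1, against 5.61 to 5.63. Pramel27 was at 4.54 in wild type female replicate 1, against 4.41 to 4.44, below detection in all. These are 4 of 76 groups tested, where 3.8 would come by chance. The heterozygote effect differed between embryo and adult for the platelet list (adjusted p = 0.000138, but adjusted p = 0.357 with an estimated correlation) and the immediate early list (adjusted p = 8.55e-06, but adjusted p = 0.0830 with an estimated correlation). Chance was not excluded for either, since 7 of 100 and 6 of 100 permutation splits gave as small a p (8.90e-06, smallest other 3.62e-09, and 2.76e-07, smallest other 2.46e-11).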

How the results depend on the processing

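The fits without litter 549, with brightness or red cell level as a covariate, and with each E12.5 signal raised to the lowest detected one of its array were chosen after the result was seen. Meis1 kept its sign in each comparison of genotypes under every alternative run, and Ppbp kept its call in homozygotes against wild types under all in which its probe was tested, with changes from -3.04 to -1.19. Apart from arrays left out, the calls in homozygotes against wild types were lost in 1 of 17 alternatives for Meis1 (adjusted p up to 0.109), 1 of 16 for Treml1 (up to 0.0698), 4 of 16 for Gp9 (up to 0.258), 6 of 16 for Alox12 (up to 0.158) and 11 of 17 for Lipa (up to 0.843). These counts leave out the raised signals, under which the 5 calls held (Ppbp -2.51, Treml1 -1.92, Gp9 -1.22, Alox12 -1.32, Lipa 0.75, adjusted p up to 0.0277), as did that of Meis1 (-1.22), while Treml1 (adjusted p = 0.128) and Gp9 (adjusted p = 0.0711) lost theirs against the midpoint. Signal over background bounds Ppbp, Treml1 and Gp9, each detected on 1 of 5 homozygote arrays. Litter as a random block was not run for the list tests, nor a chip as a block, as the files name no chip. Except where stated, the cause was not tested.

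Probe counts moved as follows. For homozygote against wild type (7) they were 3 without background correction, 4 without a probe filter, 1 with detection on all arrays, 2 with males alone and 4 without litter 549. For homozygote against heterozygote (10) they were 9 with raised signals, 6 without a filter, 2 with detection on all arrays, 4 with males alone and 2 without litter 549. For the midpoint (6) they were 4 with raised signals, 3 with an offset of 50, 0 without background correction, 3 with the authors' values, 2 without a filter, 0 with detection on all arrays, 3 without a litter term, 1 (below the midpoint) with males alone and 0 without litter 549. Median scaling gave 1 in the adult. The difference between stages gave 3 without a filter and 1 with array weights. Detection on all arrays drops platelet genes by construction, since homozygotes lie below it.

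List counts moved too. For homozygote against wild type (2) they were 0 with detection on all arrays, 4 with array weights, 4 without a litter term, 1 with males alone and 6 with the 2 genotypes alone. For heterozygote against wild type (5) they were 3 without a sex term, 2 with males alone, 2 with red cell level and 1 without litter 549. For homozygote against heterozygote (2) they were 1 without a filter, 4 with males alone and 1 without litter 549. For the midpoint (5) they were 2 with array weights, 2 with red cell level and 1 without litter 549. The adult (1) gave 2 with brightness. The stages (2) gave 5 with an offset of 50, 4 with the authors' values, 1 with detection on all arrays and 4 with the mean of a gene's probes. With an estimated correlation the 6 counts, in this order, were 0, 0, 1, 1, 0 and 0, with fry 1, 0, 1, 1, 0 and 1, and with its mixed test 7, 0, 4, 2, 5 and 1. Connective tissue genes in heterozygotes turned downward with males alone (adjusted p = 0.447).

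Meis1 stood at -1.24 in homozygotes against wild types with males alone (adjusted p = 0.109), and against heterozygotes at -0.64 with males alone (adjusted p = 0.569) and -0.84 without litter 549 (adjusted p = 0.163). Fewer arrays were fitted in these. Within litter 551 it was -1.41, -0.16 and -1.25 in the 3 comparisons, and within litter 542 -0.61 against heterozygotes. The sex difference in homozygotes turned to 0.0058 with cyclic loess. With the wild types split in 2, so that the changes shared no wild types, the correlation of homozygote and heterozygote changes was 0.00027 on average over 20 such splits (-0.21 to 0.17), in place of 0.564. Both changes still came from the same fit, with common sex and litter terms.

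With 1 array left out, probe counts ran from 5 to 9 (homozygote against wild type), 0 to 0 (heterozygote), 6 to 14 (homozygote against heterozygote), 2 to 6 (midpoint), 0 to 0 (both sex tests), 0 to 1 (adult) and 0 to 4 (stages). Lists ran from 1 to 4, 1 to 8, 2 to 5, 1 to 6, 1 to 1 and 2 to 10. Meis1 ran from -1.27 to -1.10, -0.48 to -0.35, -0.87 to -0.74, 0.14 to 0.25, -0.77 to -0.45 and 0.09 to 0.43, and in the sex tests from -0.25 to 0.12 and -0.34 to 0.021.

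Whether replicate numbers pair the samples was not settled. Arrays of different genotype and litter that share a number had a mean correlation of 0.0155 (21 pairs, from -0.457 to 0.433). Over arrays of different genotype and litter, whatever their number, the mean was lower, at -0.121 (65 pairs, from -0.586 to 0.518). These ranges overlap, and the difference was not tested. The mean was 0.398 within litters (20 pairs), and 0.0218 in adults that share a number (3 pairs). With the number as a block in place of the litter, 5 probes passed for homozygote against wild type, 10 for homozygote against heterozygote and 4 for the midpoint, and limma called 0 in heterozygotes (474 without the block at an unadjusted p under 0.05).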

Other observations

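Red cell level varied between embryos, also among those of the same genotype. The mean of 8 red cell genes other than globins ran from 7.12 (log2) in homozygote male replicate 3 to 9.46 in heterozygote male replicate 1. The lowest pair, homozygote male replicate 3 and wild type male replicate 2 (7.36), came from litter 509. Heterozygote female replicate 2 of that litter was at 8.20, and wild type male replicate 3 of litter 542 was nearly as low, at 7.47. Within litters, homozygote minus wild type stood at -0.25 (509), 0.95 (542) and 0.24 (551) for these genes.

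Among the 10 measured genes on each side of Meis1, the 4 besides Etaa1 and Fignl1 with the smallest p-values in homozygotes were Spred2, an inhibitor of growth factor signalling (0.40 ± 0.14), Grb10, an imprinted adaptor of the insulin receptor (0.26 ± 0.10), Cep68, a centrosome gene (0.30 ± 0.12), and Cobl, an actin nucleator (0.33 ± 0.15). None of these passed over the window (adjusted p from 0.0884 to 0.138, limma), and they were chosen after their values were seen.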
